A study of Mus musculus with 4 samples.

How the data were processed

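RNA was measured in CD11b-positive, CD11c-negative cells that were isolated fresh, sorted by flow cytometry and given no treatment, per the labels' protocols. There were 4 one-colour arrays, 2 for the spleen and 2 for the intestine. Each array held 45101 probe sets and was hybridised with biotin-labelled target made from total RNA, per the labels. The values used are the deposited intensity of each probe set on a linear scale. Per the submitters' processing notes, the signals were made with MAS5, the manufacturer's algorithm that summarises the probes of a set; its version is not given in the sources used here. The 2% trimmed mean was 500.003 on each of the 4 arrays, so no further scaling between arrays was applied. All values were above 0, and no pair of arrays held identical signals for a probe set. Median signals were 53.1 (spleen 1), 52.3 (intestine 1), 43.2 (spleen 2) and 54.9 (intestine 2). Arrays of a tissue are numbered in the order in which the samples are listed. Detection calls were not used here.

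The 64 control probe sets were left out. Signals under 12.1, the 25th percentile of all values pooled over the arrays, were raised to that floor before log2 was taken. The floor applied to 23.4%, 24.8%, 29.2% and 22.6% of the values of spleen 1, intestine 1, spleen 2 and intestine 2. Probe sets were kept when their mean signal over the 4 arrays was at or above the median of those means, 56.5, which left 22519. A linear model with tissue as its single term was fitted to the kept probe sets in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with trend=TRUE), and the contrast was intestine minus spleen. Tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method over all kept probe sets, and the threshold was an adjusted p of 0.05. The prior degrees of freedom came to 5.77. Folds are ratios of geometric means after the floor. Where a tissue lay under the floor on both arrays, the fold is a lower bound and is written "at least". Raising a value of the lower tissue to the floor shrinks a fold. Where both values of a tissue were raised, its own spread does not count toward the SE and the p-value.

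Of the probe sets, 34958 carried 1 gene symbol, 932 carried several and 9160 carried none; the last 2 kinds name no gene here. Gene IDs of 34754 single-symbol probe sets were found in the RefSeq table of the GRCm38.p6 assembly, and 0 symbols needed an update. That table was used only for names and for which genes lie close to each other. The array table names no genome build, so no positions are given. Each gene was represented by its kept single-symbol probe set with the highest mean signal. Of the 10403 genes kept, 4873 had over 1 kept probe set. Among genes past the threshold, 1 had another probe set that passed with the opposite sign, Rbm33.

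Gene lists were tested with limma's fry, which asks whether a list's genes move, on balance, one way, and does not compare the list with other genes. The directional p was adjusted over the 30 lists with at least 5 kept members, of 31 lists fixed. The lists covered core macrophage genes, scavenging and efferocytosis, splenic red pulp and iron handling, classical and non-classical monocytes, neutrophils, eosinophils, NK cells, dendritic cells, and mast cells and basophils. They also covered cells that the sort should not hold, namely T cells, B and plasma cells, erythroid cells, platelets and megakaryocytes, intestinal epithelium, and stroma and endothelium. The functional lists were IL-10 and TGF-beta regulation, inflammatory cytokines and mediators, chemokines, pattern recognition, MHC class II presentation, immediate early and dissociation stress genes, interferon response, alternative activation, cell cycle, lysosome, matrix remodelling and growth factors, cholesterol and lipid handling, leukocyte adhesion and chemotactic receptors, and circadian clock. Sex-linked transcripts had 3 kept members and were not tested as a list. Counts "adjusted over the list alone" use p-values adjusted over the kept members of that list.

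Named genes followed a rule. First came the 12 genes with the largest log2 difference in each direction among those past the threshold whose arrays did not overlap between the tissues, without probe sets ending in _x_at, which can bind related transcripts. Each list then gave up to 4 members past the threshold with the largest absolute difference and up to 2 members with the highest signal that did not pass. In some lists the latter lay near the highest signals of the arrays, and whether differences are compressed there was not tested. Itgam and Itgax, which encode CD11b and CD11c, were always named. Genes named outside this rule, because a count was small or the gene was singled out, were chosen after their values were seen; of the alternatives, they were run only with each array left out in turn. The groups, the comparison, the test, the lists, the naming rule and most alternatives were chosen before the data were examined.

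The alternatives were quantile normalization, scaling to a common 75th percentile, no filter, a filter at the 75th percentile, no floor, a floor at the pooled median, an offset in place of the floor, no intensity trend, a robust trend, and a block for arrays with consecutive code numbers in their titles. Others were the removal of probe sets ending in _x_at, _s_at and _a_at, limma's treat with a minimum log2 difference of 1, the mean over a gene's probe sets, camera with a preset correlation of 0.01 or an estimated one, fry's mixed test, and leaving out each array in turn. With 1 array left in a tissue, that array is assumed to vary like the other tissue's pair. The no-filter and leave-one-out settings with an offset in place of the floor were added after the data were seen. The labels do not pair the samples, so the model had no pairing term; the deviations of consecutive-code arrays from their tissue means correlated at 0.40 across probe sets, which are not independent replicates. Their intestine-minus-spleen differences had the same sign in both code pairs for 76.9% of kept probe sets and 100% of those past the threshold. The threshold itself favours probe sets whose pairs agree, so the 100% is not a separate check.

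The pipeline was tested on simulated data of 22519 probe sets in 5 runs with the same group sizes. It recovered 1.2% of 250 probe sets given a log2 change of 1, 20% at 2, 83.6% at 4 and 96.8% at 6, and 5.26% of its calls were false. For gene lists, a shifted list had all its genes raised by log2 2 in intestine, and fry called 46 of 50 such lists. Of 500 unshifted lists, 21 had an unadjusted fry p under 0.05 and 2 were called. The simulation changed a far smaller share of probe sets than was called in the data. Its lists held randomly drawn genes that varied independently. In the data, members of a list moved by unlike amounts, and the interferon response and lysosome lists were called with medians of -0.26 and 0.42. These rates therefore need not carry over to the data.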

Results

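Gene expression was measured on arrays in CD11b-positive, CD11c-negative cells sorted from the spleen and the intestine of mice. CD11b is an integrin of myeloid cells and CD11c an integrin typical of dendritic cells. The series title names the intestinal source as the lamina propria of the small intestine, and it calls both populations macrophages. There were 2 arrays per tissue and 4 in all. Signals are given as mean ± SD of the deposited intensity (n = 2 arrays), and log2 differences, intestine minus spleen, as value ± SE from limma. The labels do not say whether the arrays of a tissue came from separate animals, so each adjusted p measures only the spread between these samples. The number of arrays limits the precision.

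The comparison asks how cells sorted alike from the 2 tissues, which need not all be macrophages, differ in their transcripts. Intestinal cells had higher levels of monocyte-attracting chemokines, led by Ccl12 (at least 630.2-fold), of the anti-inflammatory cytokine Il10 (368-fold), of scavenger receptors such as Stab1 (97.8-fold), and of the complement C1q chains (30.9-fold for C1qa). Splenic cells had higher levels of neutrophil granule genes, led by Ngp (428-fold), and of genes listed for monocytes, such as Vcan (12.1-fold). Some genes of epithelium, exocrine pancreas, T cells and plasma cells, which the sort should not hold, were also higher in intestine. Of 10403 genes kept, 1637 passed the threshold, 932 higher in intestine and 705 higher in spleen. A difference of at least 4-fold was seen in 987 of them, 669 higher in intestine and 318 higher in spleen. Over probe sets, 2950 of 22519 passed, or 13.1%, with 1684 higher in intestine and 1266 higher in spleen; the smallest absolute log2 difference among them was 0.82. The median log2 difference of all kept probe sets was -0.05. Across probe sets, which are not independent replicates, signals correlated at 0.942 between the spleen arrays, at 0.937 between the intestine arrays, and at 0.785 to 0.830 between tissues. The ratio of 3' to 5' actin signal, a measure of RNA quality, was 1.69 (spleen 1), 1.95 (spleen 2), 1.80 (intestine 1) and 2.29 (intestine 2). For Gapdh it was 1.24 (spleen 1), 1.73 (spleen 2), 1.31 (intestine 1) and 1.77 (intestine 2). For both transcripts the ratio was higher on spleen 2 and intestine 2, which have consecutive codes. Without a filter limma called 0 probe sets (7373 at an unadjusted p under 0.05), and without intestine 1 or intestine 2 it also called 0 (4988 and 4322), but with an offset in place of the floor it called 2018, 2678 and 2095. A block for consecutive array codes raised the count to 6648, and a minimum log2 difference of 1 lowered it to 714.

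The largest differences toward intestine were in chemokines, Il10, a collagenase and mucosal secretory genes. Ccl12 read 6.21 ± 6.24 in spleen and 7645 ± 1019.8 in intestine, a log2 difference of 9.30 ± 0.39 (limma adjusted p = 3.23e-04). Both of its spleen values lay under the floor, so this SE and p leave out the spread between the spleen arrays. Ccl8 and Ccl7, which lie near Ccl12 on the chromosome and also attract monocytes, rose 376-fold and 318-fold (log2 8.56 ± 0.46 and 8.31 ± 0.43). Il10 rose from 20.2 ± 12.2 to 6983 ± 1839 (log2 8.52 ± 0.51, adjusted p = 3.33e-04). Mmp13, a collagenase, read 25 ± 23.3 in spleen and 8751 ± 586 in intestine, a 390.4-fold difference. Dab2, an adaptor of endocytosis, was 359-fold higher in intestine, and Rad51b, which acts in DNA repair by recombination, was 153-fold higher. Gbp2b, an interferon-inducible guanylate-binding protein, was 146-fold higher. The other 4 of the 12 genes are known from secretory epithelium or exocrine pancreas. Tff2, a mucus-associated trefoil peptide, was 569-fold higher (log2 9.15 ± 0.58), the gastrokine Gkn3 208-fold, Agr2, a disulfide isomerase of goblet cells, 187-fold, and 2210010C04Rik, a trypsinogen, 155-fold. Each of these 4 read higher on intestine 2 than on intestine 1: Tff2 at 13380.2 against 4092, and 2210010C04Rik at 6058 against 1058. The adjusted p-values of the 12 lay between 3.23e-04 and 0.00196.

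Toward spleen, the largest differences were in neutrophil genes. Ngp, a neutrophil granule protein, read 7915 ± 2505 in spleen and 14.1 ± 18.1 in intestine, a log2 difference of -8.74 ± 0.50 (adjusted p = 3.33e-04). The antimicrobial granule genes Camp, Lcn2 and Ltf were 242-fold, 132-fold and 129.7-fold higher in spleen. Cxcr2, the chemokine receptor through which neutrophils are recruited, read 4155 ± 459 against 52.0 ± 32.6. The stefin Stfa2l1 was 72.6-fold higher in spleen and Chil1, a chitinase-like protein, 79.3-fold. Wfdc21 and the acute-phase gene Orm1 differed by 129-fold and 78.1-fold. Il1f9, an interleukin-1 family cytokine, was 50.8-fold higher in spleen, Gm11346 51.6-fold, and S1pr5, a sphingosine 1-phosphate receptor of patrolling monocytes and NK cells, 44.6-fold. The adjusted p-values of these 12 genes lay between 3.33e-04 and 0.00216.

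**Figure D1:**
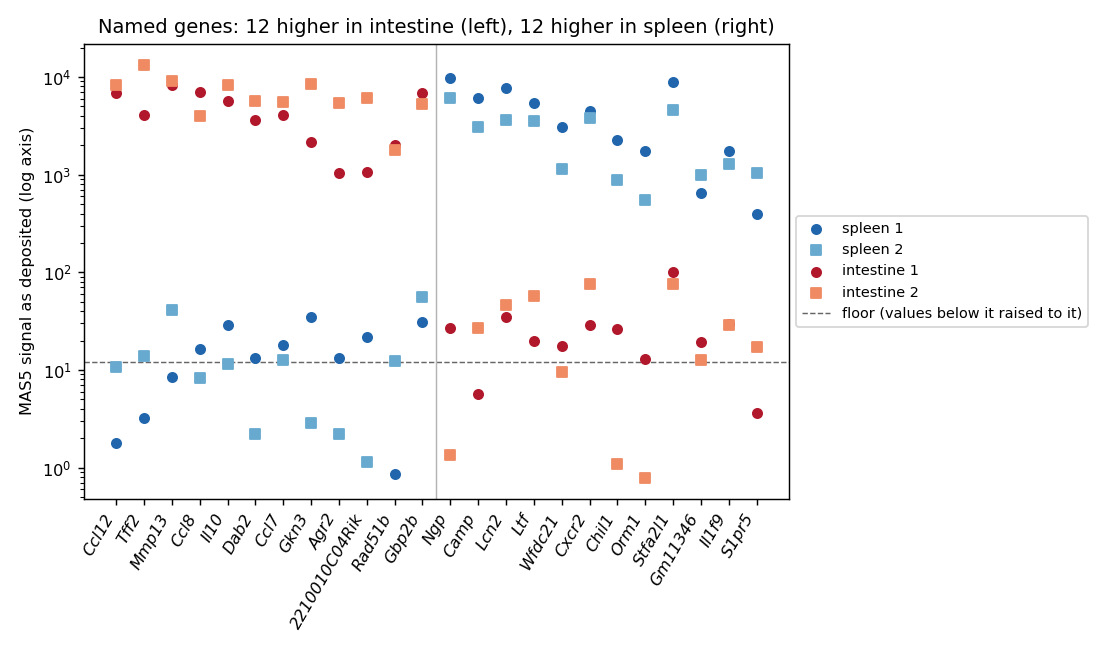
Signal on each of the 4 arrays (log axis, intensity units) for the 12 genes with the largest difference in each direction; blue marks are spleen arrays, red and orange marks are intestine arrays, and the dashed line is the floor of 12.1. Genes were chosen only where the arrays of the tissues did not overlap; Tff2, Gkn3, Agr2 and 2210010C04Rik read higher on intestine 2 than on intestine 1.

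Core macrophage genes that passed the threshold were higher in intestine. Of 18 kept members of the core macrophage list, 12 were higher in intestine, 0 were higher in spleen and 6 did not pass (13 and 0 adjusted over the list alone), with a median log2 difference of 1.29, a fry adjusted p of 0.0300 and, from camera, adjusted p = 0.195 with an estimated correlation. The complement C1q genes C1qa, C1qb and C1qc, which lie side by side, all rose: C1qa from 187 ± 41.3 to 5716 ± 4.72 (log2 4.95 ± 0.32, adjusted p = 3.90e-04), C1qc by log2 4.39 ± 0.44 and C1qb by 3.14 ± 0.27. The probe set for C1qb ends in _x_at. Cd163, the receptor for haemoglobin bound to haptoglobin, rose 9.36-fold. The lysozyme genes Lyz1 and Lyz2 did not pass, with log2 differences of -0.03 and 0.05 at mean signals between 14239 and 17795. The probe set for Lyz1 ends in _x_at and can bind related transcripts, so the 2 lysozyme readings need not be independent. That probe set gave the highest signal of any non-control probe set on spleen 1 and intestine 1 (16622 and 15184). In the scavenging and efferocytosis list, 18 of 25 members were higher in intestine and 1 was higher in spleen (19 and 1 adjusted over the list alone), with a median of 2.98, a fry adjusted p of 0.0255 and adjusted p = 0.195 with an estimated correlation. The scavenger receptor Stab1 rose from 49.2 ± 14.5 to 4731 ± 688, the lectin Cd209f rose 36.2-fold, and Gas6, a bridge between apoptotic cells and their receptors, rose 23.7-fold. The 1 member higher in spleen was Scarb1 (log2 -0.99), a lipoprotein receptor; it was named after its values were seen, as were all further genes that make up a count of 5 or fewer. Selenop and Itgav did not pass (log2 0.33 and 0.13). In the same samples the neutrophil list had a median log2 difference of -3.85.

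Genes of splenic red pulp macrophages and iron handling went both ways. Of 16 members, 5 were higher in intestine, 3 were higher in spleen and 8 did not pass (6 and 3 adjusted over the list alone; fry adjusted p = 0.231, median 0.64). Higher in spleen were Cd5l, a secreted macrophage protein (log2 -4.02 ± 0.62), Treml4 (log2 -1.43) and the iron exporter Slc40a1 (log2 -1.28). The complement component C6 was 21.7-fold higher in intestine, and Cd163, the iron transporter Slc11a2 (4.68-fold), Blvrb (log2 2.01) and the transferrin receptor Tfrc (log2 1.35) made up the rest. The ferritin chain Fth1 and Slc11a1 did not pass (log2 0.30 and 0.63).

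Monocyte and neutrophil genes that passed the threshold were higher in spleen. In the classical monocyte list 8 of 12 members were higher in spleen and 0 were higher in intestine (10 and 0 adjusted over the list alone; median -1.68, fry adjusted p = 0.0255, adjusted p = 0.195 with an estimated correlation). Haptoglobin, Hp, fell from 4518 ± 12 in spleen to 179 ± 14.8 in intestine. Cd177, Vcan and Fn1 were 20.9-fold, 12.1-fold and 9.51-fold lower in intestine. Cd177 is also a neutrophil surface protein, and which other members neutrophils express, Hp included, was not tested. Gsr and Mpeg1 did not pass (log2 -0.41 and 0.24). In the non-classical monocyte list 6 of 11 members were higher in spleen and 0 were higher in intestine (8 and 0 adjusted over the list alone; median -1.13, fry adjusted p = 0.0442, adjusted p = 0.332 with an estimated correlation). The sialoglycoprotein Spn read 5305 ± 978 in spleen and 433 ± 103 in intestine, and Ace, the integrin chain Itgal and Eno3 had log2 differences of -2.93, -2.64 and -2.20. Nr4a1, a regulator of these monocytes, did not pass (log2 -0.67 ± 0.26, adjusted p = 0.139), nor did Dusp16 (1.01). In the neutrophil list 14 of 18 members were higher in spleen and 0 were higher in intestine, and adjusted over the list alone 16 were higher in spleen and 1 in intestine (median -3.85, fry adjusted p = 0.0255, adjusted p = 0.195 with an estimated correlation). Ngp, Camp, Lcn2 and Ltf led this list too, while the gelatinase Mmp9 and the decoy receptor Il1r2 did not pass (log2 0.05 and 1.94). The spleen arrays differed for Il1r2, which read 5878 on spleen 1 and 859 on spleen 2.

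Other myeloid and lymphoid cells that a CD11b gate can hold showed no list call. Of 10 eosinophil members, 2 were higher in intestine, namely Thbs1 (log2 1.80) and Cd69 (1.51), which other leukocytes express too, and 1 was higher in spleen, the eotaxin receptor Ccr3 (-1.67); adjusted over the list alone the counts were 2 and 3 (fry adjusted p = 0.758). Siglecf and Adgre4 did not pass (log2 -0.78 and -0.38). In the mast cell and basophil list 2 of 6 members were higher in spleen (0 and 3 adjusted over the list alone; fry adjusted p = 0.111): Mcpt8, a basophil protease, at least 11.0-fold, and Hdc, the histamine-forming enzyme, 4.39-fold. Gata2 and Il4 did not pass (log2 -0.46 and -0.74). Gata2 read 449 and 1533 on the spleen arrays and 353 and 1030 on the intestine arrays, so the tissues overlapped. The filter removed 10 members, and the mean of -1.69 was -0.70 without it. In the NK cell list 1 of 12 members passed, Cd244a, higher in spleen (log2 -0.83), and adjusted over the list alone 0 passed (fry adjusted p = 0.836). Klrd1 did not pass (log2 -0.82), nor did Gzma (log2 1.56 ± 1.69), which read 21.8 on spleen 1 and 1931 on spleen 2 and had a log2 difference of -1.67 without spleen 1 and 4.80 without spleen 2. Klrd1 read 384 and 1857 on the spleen arrays and 838 and 271 on the intestine arrays, so the tissues overlapped. Of 14 dendritic cell members, 4 were higher in intestine and 1 was higher in spleen (7 and 1 adjusted over the list alone; fry adjusted p = 0.213). The chemokine Ccl22 was 20.9-fold higher in intestine, Siglech 6.99-fold, Batf3, a transcription factor of cross-presenting dendritic cells, 3.10-fold, and Kmo rose by log2 1.58, while the growth factor receptor Flt3 was 4.43-fold higher in spleen. Id2 and Dpp4 did not pass (log2 0.61 and 0.47).

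Chemokine genes rose as a group in intestine. Of 26 kept members, 18 were higher in intestine and 0 were higher in spleen (19 and 0 adjusted over the list alone), with a median log2 difference of 3.12 and a fry adjusted p of 0.0109; camera gave adjusted p = 0.195 with an estimated correlation. Besides Ccl12, Ccl8 and Ccl7, Pf4 read 52.8 ± 18.9 in spleen and 7068 ± 680.1 in intestine (log2 7.11 ± 0.38); it is a platelet chemokine that macrophages can also express. Ccl6 and Cxcl2 did not pass (log2 -0.17 and 0.48). The chemokines Cxcl1 and Cxcl3, named after their values were seen, were higher in intestine (log2 5.34 and 6.19). Without spleen 1 these differences were 6.69 and 7.72, and without spleen 2 they were 3.99 and 4.66. In the IL-10 and TGF-beta list 9 of 28 members were higher in intestine and 0 were higher in spleen, and adjusted over the list alone the counts were 15 and 1 (median 0.72, fry adjusted p = 0.0255, adjusted p = 0.195 with an estimated correlation). Along with Il10, Tgfb3 rose at least 19.2-fold, the retinoic acid-forming enzyme Aldh1a1 19.0-fold and Tgfb2 10.4-fold. Skil and the interleukin-1 antagonist Il1rn did not pass (log2 0.72 and 0.71). Inflammatory cytokines and mediators had 4 of 17 members higher in intestine and 2 higher in spleen (6 and 4 adjusted over the list alone; fry adjusted p = 0.142). Il1a was 50.7-fold higher in intestine, Il12b at least 13-fold, the costimulatory ligand Tnfsf9 7.53-fold and Tnf by log2 2.29, while Tnfsf14 was 8.14-fold higher in spleen and Csf1, the macrophage growth factor, had a log2 difference of -1.67. Ptgs2 and Il1b did not pass (log2 0.10 and 0.15) at mean signals between 12396 and 14306. In the alternative activation list 11 of 20 members were higher in intestine and 2 were higher in spleen (13 and 2 adjusted over the list alone; median 1.83, fry adjusted p = 0.0300, adjusted p = 0.195 with an estimated correlation). The lectin Mgl2 rose 40.1-fold, Socs2 21.8-fold and the folate receptor Folr2 19.2-fold, and the exceptions were Klf4 (log2 -0.97) and the chitinase-like protein Chil3 (-2.49; -3.22 without intestine 1 and -1.77 without intestine 2). Tgm2 did not pass (log2 1.23). Beside these groups stand the lower neutrophil list (median -3.85), the higher epithelial, T cell and B and plasma cell lists (medians 2.99, 3.26 and 2.30) and the stroma and endothelium list (median 2.52).

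Pattern recognition genes went both ways, with 6 of 36 higher in intestine and 5 higher in spleen (8 and 8 adjusted over the list alone; fry adjusted p = 0.478). Tlr12 was 75.7-fold and Tlr3 4.45-fold higher in intestine, and the myeloid receptors Trem1 and Trem3 were 9.19-fold and 8.31-fold higher in spleen, as were Nod1 (log2 -1.73), Tirap (-1.60) and Clec4d (-1.19). Tyrobp and Clec7a did not pass (log2 -0.28 and 0.35). MHC class II presentation had 8 of 16 members higher in intestine and 0 higher in spleen (11 and 0 adjusted over the list alone), but the list missed the threshold (fry adjusted p = 0.0956, median 1.38). The protease Lgmn rose 15.6-fold, the costimulators Cd80 and Cd86 7.88-fold and 7.41-fold, and H2-Eb1 3.55-fold, while Cd74 and Ctss did not pass (log2 1.24 and 0.19). The interferon response list was called toward spleen, with a median of -0.26 (fry adjusted p = 0.0442, adjusted p = 0.332 with an estimated correlation). In it 2 of 31 members were higher in intestine and 2 were higher in spleen (2 and 8 adjusted over the list alone). Higher in intestine were the interferon-inducible GTPase Iigp1 (17.8-fold) and the chemokine Cxcl10 (7.65-fold), and higher in spleen were Oas3 and Oasl2 (4.05-fold and 2.53-fold), of the oligoadenylate synthetase family. Trim30a and Rsad2 did not pass (log2 -0.26 and -0.14). The neutrophil, classical monocyte and non-classical monocyte lists were lower in intestine too (medians -3.85, -1.68 and -1.13). Of 35 immediate early and dissociation stress genes, 4 were higher in intestine, 2 were higher in spleen and 29 did not pass (4 and 2 adjusted over the list alone; fry adjusted p = 0.336). Myc (7.53-fold), Atf3 (2.72-fold), Gadd45b (2.50-fold) and Fosb (log2 1.16) were higher in intestine, and Klf2 (3.91-fold) and Klf4 were higher in spleen. Egr1 and Nfkbia did not pass (both log2 0.20).

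In the lysosome list 9 of 36 members were higher in intestine, 0 were higher in spleen and 27 did not pass (12 and 0 adjusted over the list alone; median 0.42, fry adjusted p = 0.00671, adjusted p = 0.195 with an estimated correlation). Besides Lgmn, the phosphatase Acp5 rose 11.1-fold, the proton pump subunit Atp6v0d2 9.20-fold and Gpnmb 6.13-fold. Lamp1 did not pass (log2 0.27). The lower neutrophil list (median -3.85) and the higher epithelial, T cell and B and plasma cell lists (medians 2.99, 3.26 and 2.30) stand beside the lysosome list. In the matrix remodelling and growth factor list 14 of 31 members were higher in intestine and 3 were higher in spleen (17 and 3 adjusted over the list alone; median 1.57, fry adjusted p = 0.0442, adjusted p = 0.268 with an estimated correlation). Along with Mmp13, the growth factor Pdgfc rose 26.5-fold and the elastase Mmp12 25.6-fold; higher in spleen were the neutrophil collagenase Mmp8 (35.9-fold), Fn1 and Adam8 (log2 -1.07). Beside this list stand the stroma and endothelium list (median 2.52, 13 of 22 members higher in intestine), whose cells also express matrix genes, and the lower neutrophil list (median -3.85). Leukocyte adhesion and chemotactic receptors had 6 of 33 members higher in each tissue (11 in intestine and 9 in spleen adjusted over the list alone; median 0.69, fry adjusted p = 0.0278 toward intestine, adjusted p = 0.345 with an estimated correlation). The anaphylatoxin receptor C3ar1 rose by log2 3.32 in intestine and the fibronectin receptor chain Itga5 by 2.58, whereas Itgal and the leukotriene receptor Ltb4r1 were 6.24-fold and 6.27-fold higher in spleen. Cd44 and Cxcr4 did not pass (log2 0.07 and 0.06). Cholesterol and lipid genes had 4 of 26 members higher in intestine and 1 higher in spleen (4 and 2 adjusted over the list alone; fry adjusted p = 0.175), and the list's median of -0.06 differed in sign from its mean of 0.38. Higher in intestine were Ch25h, cholesterol 25-hydroxylase (9.99-fold), Apoe (9.97-fold), the cholesterol exporter Abca1 (9.31-fold) and the lipid droplet protein Plin2 (2.98-fold), and Lrp1 was higher in spleen (log2 -1.16). Hmgcs1 and Fabp5 did not pass (log2 0.05 and -0.04). Of 31 cell cycle genes, 3 were higher in intestine, Tk1, Mcm6 and Mcm3 (6.64-fold, 4.02-fold and 3.18-fold), all of DNA synthesis, and 0 were higher in spleen (2 and 0 adjusted over the list alone; fry adjusted p = 0.282). Mcm4 and Pcna did not pass (log2 0.32 and 0.72). In the circadian list 1 of 14 members passed, Bhlhe40, 2.45-fold higher in intestine (1 and 0 adjusted over the list alone; fry adjusted p = 0.231); Nr1d2 and Cry1 did not (log2 0.70 and -0.88).

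Markers of cells that the sort should not hold were measured as well. In the T cell list 6 of 10 members were higher in intestine and 0 were higher in spleen (7 and 0 adjusted over the list alone; median 3.26, fry adjusted p = 0.0383, adjusted p = 0.289 with an estimated correlation). Cd28 rose at least 26.5-fold, Ctla4 24.8-fold, Cd4 22.9-fold and Il7r 22.4-fold, with intestinal signals between 321 and 883; Cd2 and Cd247 did not pass (log2 -0.44 and 0.03). A further 9 T cell genes on the array, Foxp3 and Cd8a among them, lay under the filter, and the list's mean log2 of 2.58 was 1.35 with no filter and an offset in place of the floor. In the B and plasma cell list 8 of 16 members were higher in intestine and 1 was higher in spleen (10 and 1 adjusted over the list alone; median 2.30, fry adjusted p = 0.0491, adjusted p = 0.223 with an estimated correlation). The plasma cell genes Tnfrsf17, Mzb1 and Sdc1 rose 17.1-fold, 9.39-fold and 7.10-fold, as did the adaptor Blnk (9.39-fold), while Ms4a1, which encodes the B cell antigen CD20, had a log2 difference of -2.79 (-3.80 without spleen 1 and -1.78 without spleen 2). Irf4 and Xbp1 did not pass (log2 0.30 and -0.15). With the 7 members under the filter included, the mean of this list was 0.96 in place of 1.70. In the intestinal epithelium list 13 of 23 members were higher in intestine and 0 were higher in spleen (16 and 0 adjusted over the list alone; median 2.99, fry adjusted p = 0.0255, adjusted p = 0.195 with an estimated correlation). Besides Agr2, Tspan8 rose 77.7-fold and the secreted lectin-family proteins Reg1 and Reg3b rose at least 44.2-fold and at least 20.3-fold. The intestine arrays differed for both: Reg1 had a log2 difference of 6.70 without intestine 1 and 4.23 without intestine 2, and Reg3b 2.44 and 6.25. Lgals4 and Cdh1 did not pass (log2 0.02 and 1.17). The filter removed 13 epithelial members, such as Muc2 and Krt20, and the mean of 2.84 was 2.13 with no filter. Stroma and endothelium had 13 of 22 members higher in intestine and 1 higher in spleen, Ncam1 (log2 -1.40), with 14 and 1 adjusted over the list alone, but the list missed the threshold (fry adjusted p = 0.0847, median 2.52). Dcn, Col3a1 and Col1a1, of the extracellular matrix, and the endothelial receptor Tek were 27.1-fold, 25.8-fold, 20.7-fold and 20.1-fold higher in intestine. Flt1 and Acta2 did not pass (log2 -0.80 and 0.77). Flt1 read 931 and 2073 on the spleen arrays and 380 and 1667 on the intestine arrays, so the tissues overlapped. In the platelet and megakaryocyte list 3 of 6 members were higher in intestine and 2 were higher in spleen (4 and 2 adjusted over the list alone; median 2.08, fry adjusted p = 0.00671, adjusted p = 0.345 with an estimated correlation). Pf4, Clec1b (8.06-fold) and Ppbp (5.75-fold) were higher in intestine, and Rgs18 (8.62-fold) and Itgb3 (log2 -2.50) were higher in spleen; Vwf did not pass (log2 1.64). Another 7 platelet genes, such as Itga2b and Gp9, lay under the filter, and the mean of 1.45 was 0.50 with no filter. The erythroid list had 2 of 6 members higher in each tissue (3 in intestine and 2 in spleen adjusted over the list alone; fry adjusted p = 0.227). Ermap (31.0-fold) and Tspan33 (6.43-fold) were higher in intestine, and the globin Hbb-b2 (19.0-fold) and the red cell anion exchanger Slc4a1 (9.03-fold) were higher in spleen; Hba-a2 and Car2 did not pass (log2 -0.43 and 1.82).

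**Figure D2:**
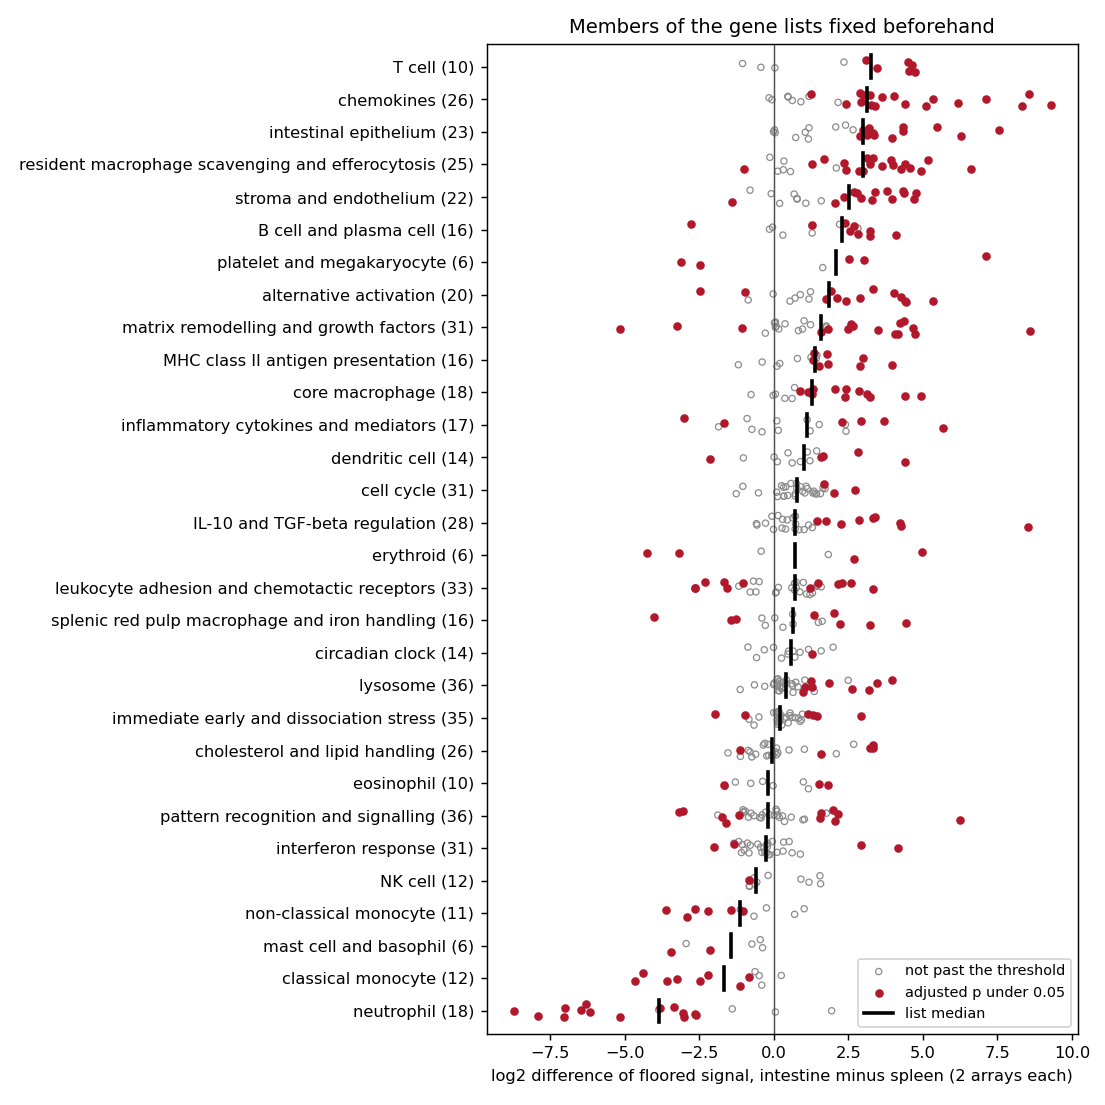
Log2 difference (intestine minus spleen) of each kept member of the 30 tested gene lists; filled red dots are members past the threshold and black bars are list medians. The bar of the chemokine list lies at 3.12 and that of the neutrophil list at -3.85.

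The sorting genes did not pass the threshold. Itgam, which encodes CD11b, read 237 ± 129.7 in spleen and 126 ± 7.17 in intestine (log2 -0.80 ± 0.53, adjusted p = 0.387). Itgax, which encodes CD11c, read 1745 ± 1071 in spleen and 4245 ± 221 in intestine (log2 1.43 ± 0.42, adjusted p = 0.0635). Its spleen arrays read 988 and 2502, so the size of the difference rests on which is used. Itgax read above Itgam in both tissues although the gate was CD11c-negative. Neither gene had a further probe set, and signals of different probe sets were not calibrated against each other. These values therefore do not check the sort. Of 3 kept sex-linked transcripts 0 passed, also adjusted over the list alone; the Y-linked genes Eif2s3y and Kdm5d had log2 differences of -0.02 and -0.28.

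Of the 30 lists, 16 passed fry's directional test, 12 toward intestine and 4 toward spleen, and 27 passed its mixed test, which counts changes in either direction. Camera called 19 lists with a preset correlation of 0.01 and 0 with an estimated one (5 at an unadjusted p under 0.05), the block for array codes left 2, and without 1 array fry called 0 or 1 (6 to 9 at an unadjusted p under 0.05). With no filter alone, 2 of the 16 lists lost their call, and so did all 118 named genes past the threshold. With the minimum log2 difference, 82 of the 118 passed. Of the 16 lists, each run in 9 or 10 further settings, 5 lost their call in at least 1: B and plasma cell, T cell, interferon response, adhesion receptors, and matrix remodelling. The stroma and endothelium list gained one without probe sets ending in _x_at, _s_at and _a_at. Of the 118 named genes past the threshold, each kept in 8 to 10 of those settings, 91 also passed wherever they were kept, and 27 did not pass in at least 1: Ace, Atf3, Atp6v0d2, Batf3, Bhlhe40, Ccl22, Ccr3, Cd244a, Cd69, Flt3, Gadd45b, Gpnmb, H2-Eb1, Hdc, Il12b, Klf2, Mcm3, Mcm6, Mcpt8, Mzb1, Oasl2, Reg3b, Siglech, Slc4a1, Tgfb2, Thbs1 and Tk1. Leaving out 1 array moved the fold of 45 of the 118 by over 1.5 times and changed the sign of 0: 2210010C04Rik, Ace, Agr2, Aldh1a1, Atp6v0d2, Blnk, C1qc, C6, Ccl22, Cd163, Cd4, Cd80, Ch25h, Chil1, Col1a1, Col3a1, Cxcr2, Fn1, Gkn3, H2-Eb1, Hdc, Iigp1, Il10, Il1a, Il7r, Klf2, Ltf, Mcm6, Mmp12, Mmp13, Mzb1, Orm1, Pdgfc, Reg1, Reg3b, S1pr5, Siglech, Slc4a1, Tek, Tff2, Tgfb2, Thbs1, Tk1, Vcan and Wfdc21. The largest such move was that of Reg3b, by log2 1.90. The unchanged signs are favoured by the choice of genes past the threshold. A single change of filter or floor moved the mean of 7 lists by over 1.5 times: the 5 whose means are given above with the members under the filter, chemokines (2.86 to 3.93) and stroma and endothelium (1.44 to 2.66). With no filter and an offset together, the neutrophil mean of -4.26 became -3.63. Leaving out 1 array moved the NK cell mean alone by that much, to -1.20 without spleen 1 and 1.17 without spleen 2; with the offset as well, the neutrophil mean reached -3.62 without spleen 1 and the stroma and endothelium mean 1.52 without intestine 2.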

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

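The settings with an offset in place of the floor, combined with no filter or with an array left out, were chosen only after the data were seen. Counts are given in the order probe sets past the threshold, probe sets higher in intestine, probe sets higher in spleen, genes past the threshold and gene lists past the threshold; the reported counts were 2950, 1684, 1266, 1637 and 16. They stayed within 1.5 times under quantile normalization, scaling to the 75th percentile, no floor, a floor at the median, an offset, a robust trend and without probe sets ending in _x_at, _s_at and _a_at (2243 to 3009 probe sets), and the mean over a gene's probe sets gave 2160 genes. With no filter limma called 0, 0, 0 and 0 genes, with 7373 probe sets at an unadjusted p under 0.05, because 3761 probe sets lay at the floor on every array with no spread and the prior degrees of freedom fell to 0.883; with an offset added, 2018 passed, 1218 toward intestine and 800 toward spleen. A filter at the 75th percentile, which tests fewer probe sets, gave 1796, 924, 872, 1085 and 10. Without the trend, 802 were higher in spleen and 1079 genes passed; the cause was not tested. The block for array codes, with 1 residual degree of freedom, gave 6648, 3365, 3283, 3418 and 2, and all 2950 reported probe sets were among its calls. The block also called 18 named genes that had not passed the threshold. A minimum log2 difference of 1 by construction gave fewer: 714, 499, 215 and 434. Camera with an estimated correlation called 0 lists (5 at an unadjusted p under 0.05) and fry's mixed test, which also counts opposite changes, 27. Leaving out 1 array gave 0 to 3144 probe sets, 0 to 1922, 0 to 1222, 0 to 1627 genes and 0 to 1 lists. The 0 came without intestine 1 or intestine 2, where 121 probe sets at the floor had no spread (4988 and 4322 at an unadjusted p under 0.05); with the offset 2678 and 2095 passed. Without spleen 1 or spleen 2, 3144 and 3003 passed. The 1 list was classical monocyte, without intestine 2; among the 4 settings 6 to 9 lists had an unadjusted p under 0.05. Gzma, not past the threshold, ranged from a log2 of -1.67 without spleen 1 to 4.80 without spleen 2, since its spleen arrays read 21.8 and 1931. Of the 118 named genes past the threshold, 96 also passed in all 4 leave-one-out settings with the offset, all 118 with the block, and 82 with the minimum difference. Signal over background limits the low end: 75 genes past the threshold lay at the floor on both spleen arrays and 5 on both intestine arrays (Mcpt8, Ankrd22, Ccdc146, Slc16a14 and 4931428L18Rik), so their folds are lower bounds.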

Other observations

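The 5 gene groups below and all 4 tests of explanations were chosen only after the results were seen, and the groups were not tested as sets. Of 16 kept complement genes, 9 were higher in intestine, 0 were higher in spleen and 7 did not pass, among them Cd55 (log2 -1.70), Cr1l (-0.29) and C5ar1 (0.15). Besides the C1q genes, C6 and C3ar1, which the fixed lists hold too, the C1 inhibitor Serping1 read 19.9 in spleen and 266 in intestine (log2 3.78; 4.46 without spleen 1 and 3.10 without spleen 2), and properdin, Cfp, read 1581 ± 193 and 3376 ± 359 (log2 1.10). In a group of 11 kept Fc receptors, related genes and the ficolins Fcna and Fcnb, which are not Fc receptors, 5 were higher in intestine, namely Fcgr1, Fcgr2b, Fcgr4, Fcgrt and Fcrls (at least 99.3-fold), and 1 was higher in spleen, Fcnb (log2 -4.96; -3.86 without spleen 1 and -6.06 without spleen 2). In a group of 32 transcription factors chosen for the macrophage lineage, 8 were higher in intestine and 3 were higher in spleen. The 8 include Batf3, which the dendritic cell list holds too, and the T cell list was also higher in intestine (median 3.26). Which cells in the samples expressed these factors was not tested. Runx3 read 428 ± 86.7 in spleen and 2147 ± 157 in intestine, and Creb5 read 10.7 and 853 (log2 6.65 without intestine 1 and 5.35 without intestine 2). The 3 higher in spleen were Cebpd (log2 -2.25), Klf4 (-0.97) and Id1 (-1.78).

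A group of 12 kept genes was chosen for gastric and duodenal gland mucosa. In it 5 were higher in intestine, Tff2, Gkn3, Agr2, Gcnt3 and Ang4, and 0 were higher in spleen. Not all of these are particular to such glands, since Agr2 also belongs to the intestinal epithelium list. The probe sets for Ang4 and Gkn1 end in _x_at. All 5 read higher on intestine 2 than on intestine 1, by a median log2 of 1.91. Of the 7 that did not pass, Gkn1, Gkn2 and Tff1 went the other way, reading 342, 283 and 148 on intestine 1 and 26.5, 2.91 and 27.8 on intestine 2, and Galnt6, Bace2, Aqp5 and Ctse read higher on intestine 2. Of the 13 called members of the intestinal epithelium list, 5 read higher on intestine 2, with a median log2 of -0.11.

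Of 15 kept genes of the exocrine pancreas, 14 were higher in intestine and Pla2g1b did not pass (adjusted p = 0.0593); 2210010C04Rik, with the highest signal, read 1058 on intestine 1 and 6058 on intestine 2, and Prss2 398 and 2528. Binding of 1 protease transcript to the probe sets of its relatives was tested by counting called members outside the serine protease family, and the 7 found argue against it as the whole cause. All 14 read higher on intestine 2, and their median shift between the intestine arrays exceeded that of the 12 called core macrophage genes by log2 2.25 (95% bootstrap interval over genes 1.99 to 2.69, 10000 draws). Pancreatic RNA carried into the samples, from cells that sorting for CD11b should remove, and a difference between the tissues cannot be told apart, because that gap restates the pattern on 1 array against 1 and its interval covers only genes that move together. How many of these genes small intestinal cells express themselves was not tested.

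The core macrophage list was higher in intestine while the neutrophil list was lower, and neutrophils pass a CD11b gate. A smaller neutrophil share in the intestinal gate would raise alike the genes of every other cell type that neutrophils do not express. The median log2 difference of core macrophage genes exceeded that of non-classical monocyte genes by 2.60 (95% bootstrap interval over genes 1.74 to 4.85). The lists had 17 and 10 members, with the shared Cx3cr1 left out. That gap restates list medians seen before the test was chosen, and its interval covers the spread between genes, not between arrays. Which of these genes neutrophils also express was not tested, so the gap cannot decide whether that share is the whole cause. That share stays open, as do a lower monocyte share and a difference between macrophages of the tissues, which were not tested.

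The chemokine list was higher in intestine, and handling of the tissue during isolation could induce such genes. The immediate early and dissociation stress list had a median log2 difference of 0.20 (fry adjusted p = 0.336), with 4 members higher in intestine and 2 higher in spleen. Handling and tissue cannot be told apart, because these members went both ways and no sample separates isolation from tissue.

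The 9 spiked-in control probe sets had geometric mean signals of 6399 (spleen 1), 6398 (intestine 1), 10478 (spleen 2) and 14227 (intestine 2), a 1.17-fold difference between tissues and a 1.91-fold difference between the arrays with codes 20 and 21 and those with 3 and 4. The best-measured probe set of the Y-linked gene Eif2s3y read between 3886 and 8669 on the 4 arrays, and all probe sets of Xist read at most 38.4.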
